A study of Homo sapiens with 68 samples.

How the data were processed

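Total RNA from CD14-positive cells of 68 human donor samples was sequenced, in 4 groups taken from the labels: 14 healthy bone marrow donors (NBM), 8 samples of polycythemia vera (PV), 15 of essential thrombocythemia (ET) and 31 of myelofibrosis (MF). Per the labels, cells were first depleted of CD34-positive cells, then bound with CD14 beads, and RNA was isolated by column with a DNase step and sequenced on a NovaSeq instrument. The deposited table holds raw counts per gene symbol, made by the authors and not normalized, with whole numbers in each of its 68 columns. The submitters' processing notes name bcl2fastq, STAR 2.5.1a and edgeR, and the GRCh38 build. The counting program, the annotation release and the strand setting are not given in the sources used here. Values of genes that share reads with near copies are therefore uncertain, such as HBB and HBD, the H4C3 histone family, HLA and immunoglobulin genes, PF4 and PF4V1, CXCL1, CXCL2 and CXCL3, FCGR3A and FCGR3B, and mitochondrial genes with nuclear copies. The same holds for genes that overlap another gene on either strand.

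Of 59653 symbols, 56586 matched GENCODE release 29, which gave gene positions, classes and GC content. XIST, TSIX and Y-linked symbols, 518 in all, were left out of every step. Of the 59135 left, edgeR's filterByExpr kept 24654 for testing, and these held 99.9467% of counts. Total counts per library ran from 14842000 to 59633000 (rounded to 5 digits). At that depth the spread between donors, rather than counting error, is the larger source of error for genes at 4 log2 CPM or more. Values in log2 CPM used TMM factors and a prior count of 2. No pair of libraries had identical counts, and the highest correlation between 2 libraries was 0.975 against a median of 0.936. Each library was taken as a separate donor, and p-values measure the spread between libraries. Replicate numbers are names and pair no samples. No other donor feature was used.

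Comparisons were MF, PV and ET each against NBM, and MF against ET, MF against PV and PV against ET, all from 1 edgeR 4.0.16 quasi-likelihood fit of the 68 libraries (TMM, trended dispersion, robust) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and those changed by at least 1 on the log2 scale were also counted. Errors of log2 fold changes are SE derived from the fit, and 95% intervals assume a normal spread. After a median over several genes, ± gives the median SE of those genes singly, not an error of the median. A p adjusted over the list alone is the edgeR p adjusted within the members of that list. Called here and past the threshold refer to these tests.

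Lists of genes were tested with camera (limma 3.58.1) on log2 CPM, adjusted over 35 lists, 22 for monocyte programs and 13 of markers of other cells the bead fraction may hold, with a preset correlation between genes of 0.01. That preset makes the test liberal where list members move together, so the adjusted p with an estimated correlation is given beside each described list. Lists overlap, and monocytes express many of the genes of the macrophage, mature neutrophil and dendritic cell lists. Genes called in all 3 diseases were counted per direction. They were compared with independent lists, with 10 simulations without an effect that shared simulated NBM libraries, and with random divisions of the NBM libraries. Genes were named by a rule: adjusted p under 0.05, a mean of at least 4 log2 CPM, and at least 80% of the libraries of the first group on the side of the second group's median that the change gives. The 10 largest changes per direction against NBM and the 5 largest between diseases were taken, without HLA genes and antigen receptor segments. RPS6KA1, RPS6KA2, RPS6KA3, RPS6KA6 and DUSP6 were always named, and so were up to 4 members of each list described, those with the smallest adjusted p. Not every gene that the rule gave is printed. The groups, lists, tests and naming rule were set before the data were examined.

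The pipeline was tested on simulated data, with 200 changed genes per comparison. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 43.3%, 77.6% and 98.5% in MF, 23.9%, 61.2% and 95.5% in PV, and 44.8%, 79.1% and 100% in ET against NBM. It called 5, 6 and 8 unchanged genes.

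The last 10 libraries of the table formed a technical set, found from the data and not given in the labels. The log2 difference between set and other libraries rose with GC content across 9151 protein-coding genes (Spearman rho 0.772). A signature of 100 genes per direction, drawn from NBM libraries only, placed all 8 patient libraries of the set (lowest score 3.73) above all 46 outside it (highest 3.41). GC slopes ran from 0.232 to 0.490 in the set and from -0.296 to 0.342 outside, where 1 library lay above the lowest in the set. Because the set holds 7 of 15 ET, 2 of 14 NBM, 1 of 31 MF and 0 of 8 PV libraries, it is partly confounded with the groups.

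Alternatives set before the data were examined were DESeq2 size factors and upper-quartile factors in the same fit, no low-count filter, a stricter filter (at least 10 counts in 90% of libraries), the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit of only the groups compared, glmTreat against a fold of 1.5, and other-cell genes left out of the counts. Added terms were 6 other-cell scores (T, B, NK, erythroid, platelet and megakaryocyte, and neutrophil precursor markers), the replicate number as a block, and log2 library size. For lists, an estimated correlation and the fry test were also set beforehand. Alternatives chosen after seeing the data were the technical set as a term, only the 58 libraries outside it, the GC slope of each library, the log2 mitochondrial share, and leaving out the library of lowest depth or the PV library of highest platelet, highest macrophage or lowest glycolysis score, 1 at a time. Groups of 8 libraries were checked for single far values, and 30 splits of the libraries per comparison were compared with the real one. Isoforms, mutations and antisense transcripts were left out, since counts per symbol cannot resolve them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.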

Results

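Total RNA was sequenced from CD14-positive cells, the bead-selected fraction in which monocytes are expected to prevail, after CD34-positive cells had been removed. The 68 libraries fell into 4 groups per the labels: myelofibrosis (MF, n = 31), essential thrombocythemia (ET, n = 15), polycythemia vera (PV, n = 8), and healthy bone marrow donors (NBM, n = 14). MF, ET and PV are myeloproliferative neoplasms, clonal blood cancers that overproduce myeloid cells. Per the series design, patient cells came from blood mononuclear cells and healthy cells from bone marrow. Total counts per library, rounded to 5 digits, ran from 14842000 to 59633000, with medians of 41657000 in NBM, 36858000 in PV, 34265000 in ET and 45372000 in MF. Mitochondrially encoded genes held 5.73 ± 1.14% of counts in NBM, 9.89 ± 4.09% in PV, 10.7 ± 3.56% in ET and 7.27 ± 6.06% in MF (mean ± SD). The last 10 libraries of the table stood apart in their GC content profile. They comprised 2 NBM, 7 ET and 1 MF library and no PV library, and are called the technical set here.

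The series title names RSK1, a kinase that acts downstream of ERK, and the first question was whether its gene differed between the groups. RPS6KA1 (RSK1; GRCh38 chromosome 1, 26529761 to 26575030, protein coding) was abundant in every group, at 7.58 ± 0.32 log2 CPM in NBM (SD, n = 14), 7.24 ± 0.50 in PV (n = 8), 7.50 ± 0.38 in ET (n = 15) and 7.49 ± 0.50 in MF (n = 31). It passed the test in none of the 6 comparisons. Its log2 fold change was -0.04 ± 0.13 (SE) in MF against NBM (adjusted p = 0.903, 95% interval -0.30 to 0.22), -0.30 ± 0.19 in PV against NBM (adjusted p = 0.509, -0.67 to 0.06) and -0.06 ± 0.16 in ET against NBM (adjusted p = 0.925, -0.37 to 0.24). The edgeR p adjusted over the list alone, that of RSK and ERK kinases, was 0.847, 0.359 and 0.822. Between the diseases it was 0.02 ± 0.13 in MF against ET, 0.26 ± 0.17 in MF against PV and -0.24 ± 0.18 in PV against ET. In NBM both libraries of the technical set stood at 8.07 log2 CPM, above the highest of the other 12 (7.92). Comparisons with ET, of which the set holds 7 of 15 libraries, may therefore shift with the set. With the set as a term, chosen after seeing the data, PV against ET went from -0.24 to 0.02. In the 58 libraries outside the technical set, an alternative also chosen after seeing the data, RPS6KA1 stood at 0.03 in MF against NBM and passed in no comparison. RPS6KA3 (RSK2) passed in no comparison either, with values between -0.28 ± 0.15 in PV and -0.18 ± 0.10 in MF against NBM. RPS6KA2 (RSK3) was near the low end of expression, at 1.29 ± 0.58 log2 CPM in NBM, and RPS6KA6 (RSK4), with 192 counts over all libraries, was too low to test. DUSP6, the phosphatase that switches ERK off and is itself induced by ERK, stood at 9.31 ± 0.70 log2 CPM in NBM and 9.85 ± 0.92 in MF, a change of 0.68 ± 0.28 that missed the threshold (adjusted p = 0.129). In PV and ET against NBM, DUSP6 values were 0.24 ± 0.37 and -0.13 ± 0.32.

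**Figure D1:**
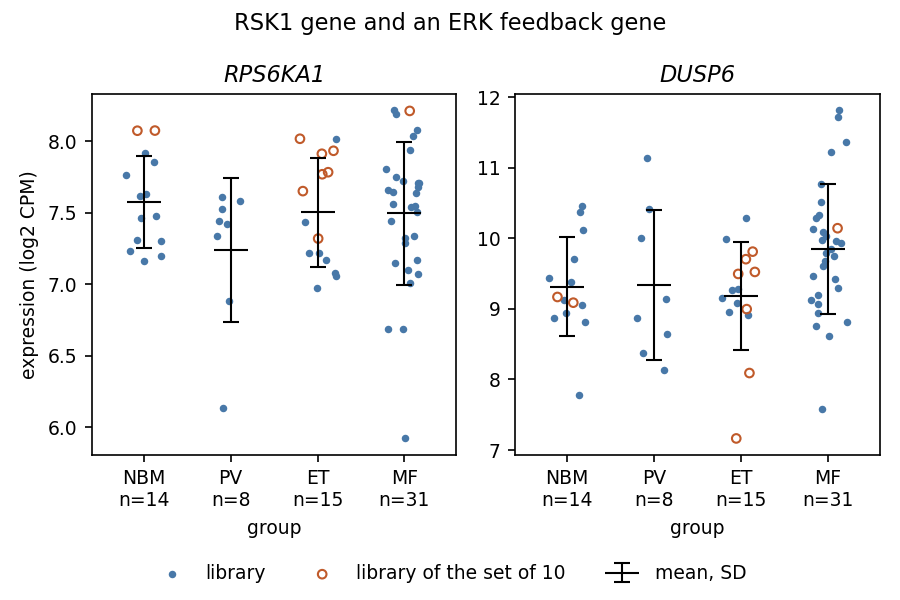
Expression in log2 CPM (vertical axis) of RPS6KA1 and DUSP6 by group, with 1 point per library, open circles for the 10 libraries of the technical set, and the mean with its SD. RPS6KA1 means lie between 7.24 and 7.58 in the 4 groups, with overlapping libraries.

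MF against NBM asked which genes differ in the CD14-positive fraction of myelofibrosis from that of healthy donors. Most platelet genes and some interferon and ERK-induced genes were higher in MF (n = 31) than in NBM (n = 14), and some cell-cycle, erythroid, B cell and plasma cell genes were lower. Of 18 lists called, 1 kept its call with an estimated correlation, that of platelet markers. PPBP, a chemokine precursor of platelet granules, rose by 6.12 ± 0.70 on the log2 scale (69.5-fold, adjusted p = 3e-09) and exceeded the NBM median in 100% of MF libraries. PF4, another platelet chemokine, rose by 5.36 ± 0.65, the platelet receptor gene MPIG6B by 4.16 ± 0.53, and ITGA2B, the platelet integrin alpha IIb, by 3.45 ± 0.55. In all, 21 of 22 platelet and megakaryocyte markers rose and none fell, with a median of 3.80. With an estimated correlation that list had adjusted p = 0.000855. CLU, which platelets also carry, rose by 2.84 ± 0.45. Platelets carried over in the fraction cannot be told apart here from a change in the monocytes.

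Interferon genes formed the next group. Of 22 interferon gamma response genes 15 rose in MF, 19 when adjusted over the list alone, with a median of 1.41 (adjusted p = 0.231 with an estimated correlation). CD274, the checkpoint ligand PD-L1, rose by 4.94 ± 1.12, GBP5 and GBP1, which encode interferon-induced guanylate-binding proteins, by 3.11 ± 0.84 and 2.62 ± 0.71, and WARS1 by 1.80 ± 0.47. Of 34 type I interferon response genes 13 rose, 30 adjusted over the list alone, with a median of 1.07 (adjusted p = 0.135 with an estimated correlation). IFIT5 rose by 1.43 ± 0.30 and IFI27 by 4.30 ± 1.14. Genes of MHC class II presentation rose in 8 of 15 cases, 10 adjusted over the list alone, and HLA-DPA1 rose by 1.10 ± 0.28 (list adjusted p = 0.344 with an estimated correlation). C1QA, a complement component made by macrophages, rose by 2.44 ± 0.67.

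Of 20 ERK-induced and feedback genes 6 rose in MF, 8 adjusted over the list alone, with a median of 0.56 (adjusted p = 0.21 with an estimated correlation). The transcription factor genes EGR2 and EGR3, which ERK induces, rose by 2.90 ± 0.58 and 2.65 ± 0.61, and SPRY2, a brake on growth factor signalling, by 2.42 ± 0.60. Of the 20 RSK and ERK kinases 2 rose, among them the scaffold gene KSR1 by 0.36 ± 0.11, and 3 did when adjusted over the list alone (median 0.11, adjusted p = 0.135 with an estimated correlation). Among 24 JAK-STAT targets 10 rose and 1 fell, with the kinase gene PIM1 up by 2.40 ± 0.47, and among 33 TNF and NF-kB targets 12 rose and 1 fell, with TNF up by 1.63 ± 0.38. Both lost their call with an estimated correlation (adjusted p = 0.243 and adjusted p = 0.643), and counts adjusted over the list alone were 12 and 15 higher. Fibrosis-linked secreted and matrix genes rose in 8 of 28 cases, among them PDGFA (4.22 ± 0.57) and PDGFB (3.28 ± 0.53), growth factors that platelets store, and SLAMF7 (2.41 ± 0.56). That list had 11 higher and 2 lower members adjusted over the list alone (adjusted p = 0.118 with an estimated correlation).

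Some monocyte subset genes changed, and neither subset list kept its call with an estimated correlation. Non-classical monocyte genes rose in 8 of 21 cases, 15 adjusted over the list alone, with TCF7L2 at 1.20 ± 0.18 and CKB at 2.26 ± 0.38 (adjusted p = 0.0679 with an estimated correlation). Classical monocyte genes fell in 5 of 21 cases and rose in none, with S100A12 at -1.30 ± 0.19 and S100A8, another calcium-binding alarmin, at -0.71 ± 0.14. Adjusted over the list alone, 10 classical genes were lower and 2 higher (adjusted p = 0.135 with an estimated correlation). ALOX5AP, needed for leukotriene synthesis, was lower at -1.49 ± 0.22, and so were the nuclear receptor gene NR4A2 (-1.81 ± 0.24), HP (haptoglobin, -1.41 ± 0.47), RPH3A (-1.35 ± 0.36), NUAK2 (-1.25 ± 0.28) and VNN3 (-1.20 ± 0.27). HP was close to the threshold, and lost its call at adjusted p = 0.0504 without the PV library of highest macrophage score and 0.0501 without that of lowest glycolysis score, both left out after seeing the data.

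Of 32 cell-cycle genes 21 fell in MF and none rose, 25 adjusted over the list alone, with a median of -1.21 (adjusted p = 0.118 with an estimated correlation). The mitotic genes TOP2A and AURKB stood at -2.40 ± 0.37 and -1.73 ± 0.24, and the replication-dependent histone gene H4C3 at -1.47 ± 0.22. Of 22 erythroid markers 12 fell and 3 rose, adjusted over all genes or over the list alone, with HBB (beta globin) at -2.82 ± 0.65. Of 19 B cell markers 6 fell and 1 rose, and DNTT, the terminal transferase of early lymphoid cells, stood at -7.07 ± 0.67. Of 14 plasma cell markers 5 fell and 1 rose, with the immunoglobulin gene IGKC at -2.95 ± 0.71. Adjusted over the list alone, 8 B cell and 6 plasma cell markers were lower. Erythroid, B cell and plasma cell lists had adjusted p = 0.118, adjusted p = 0.179 and adjusted p = 0.118 with an estimated correlation. MPO, the granule enzyme of neutrophil precursors, fell by 2.13 ± 0.34 on the log2 scale and lay below the NBM median in 100% of MF libraries.

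The edgeR test called 2136 of 24654 genes in MF against NBM, 1272 higher and 864 lower, and 1168 of them changed by at least 1 on the log2 scale. limma voom called 3738, 1619 higher and 2119 lower. With the 6 other-cell marker scores as covariates 6 genes passed. The median fold in the called direction of the 2136 genes moved from 1.10 to 0.669, and the median SE of those genes from 0.285 to 0.529. Within the 58 libraries outside the technical set 2049 genes passed, 1655 of them among the 2136, and 2802 passed with the set as a term, both chosen after seeing the data, while disease and tissue cannot be separated in this comparison.

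**Figure D2:**
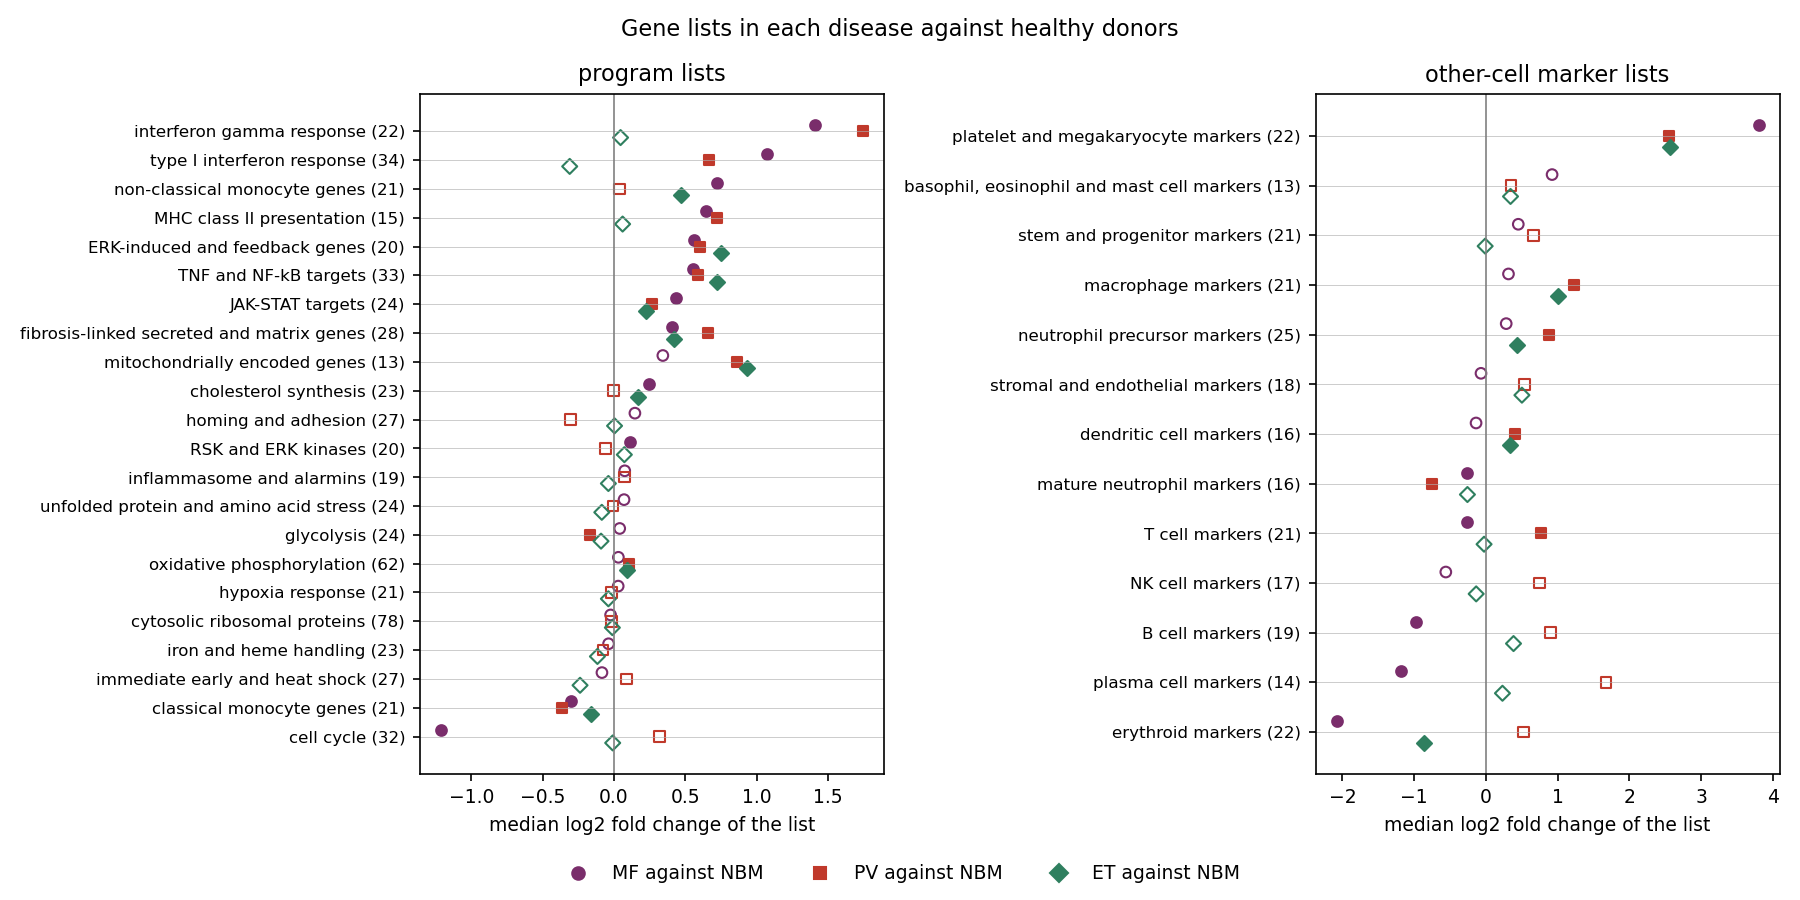
Median log2 fold change (horizontal axis) of each gene list in MF, PV and ET against NBM, with the number of measured genes in brackets, filled marks for lists past the camera threshold with the preset correlation and open marks for the others. The platelet and megakaryocyte list has medians of 3.80, 2.55 and 2.57, and the cell cycle list falls to -1.21 in MF.

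PV against NBM asked the same for polycythemia vera. Some macrophage, interferon gamma and platelet genes were higher in PV (n = 8) than in NBM (n = 14), and the calls in each of these lists depended on 1 library. No list was called with an estimated correlation. CXCL10, a chemokine induced by interferon gamma, rose by 4.98 ± 1.23 (31.6-fold, adjusted p = 0.019) and lay above the NBM median in 87.5% of PV libraries. In 3 of 8 PV libraries it lay above every NBM library, and mean log2 CPM differed by 3.35. The complement genes C1QA and C1QB rose by 4.07 ± 0.82 and 4.12 ± 0.91, PPBP by 4.56 ± 0.70 and EGR2 by 3.96 ± 0.69. CD69, an early activation antigen of lymphocytes and other leukocytes, rose by 3.60 ± 0.79, GBP5 by 3.61 ± 0.97, GBP1 by 3.15 ± 0.84, PF4 by 3.38 ± 0.66 and SLAMF7 by 2.83 ± 0.66. Without the PV library of highest platelet score, left out after seeing the data, PPBP stood at 2.01 ± 0.58 (adjusted p = 0.0622) and PF4 at 1.12 ± 0.58 (adjusted p = 0.438), neither called. Without that of highest macrophage score, also left out after seeing the data, EGR2, PPBP and PF4 kept their calls. CXCL10 (4.21 ± 1.21, adjusted p = 0.0941), C1QA (2.66 ± 0.78), C1QB (2.45 ± 0.86), CD69 (2.81 ± 0.78), GBP5 (2.997 ± 0.970), GBP1 (2.53 ± 0.84) and SLAMF7 (2.34 ± 0.67) lost theirs, with adjusted p from 0.0774 to 0.221.

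Among 22 interferon gamma response genes 8 rose in PV, with a median of 1.74, and 19 did when adjusted over the list alone. The feedback inhibitor gene SOCS1 rose by 5.13 ± 1.20 and IDO1, which degrades tryptophan, by 4.94 ± 1.24. Type I interferon genes rose in 3 of 34 cases, IFIT5 by 1.47 ± 0.38, IFI27 by 4.68 ± 1.28 and the RNA sensor gene IFIH1 by 1.01 ± 0.28, and 8 passed when adjusted over the list alone. MHC class II genes rose in 2 of 15 cases, HLA-DOA by 1.89 ± 0.45 and HLA-DPA1 by 1.26 ± 0.36, and 8 passed when adjusted over the list alone. Each of these 3 lists had adjusted p = 0.271 with an estimated correlation, and without the PV library of highest macrophage score 0 of their genes were called in edgeR, with medians of 1.37, 0.44 and 0.54. Of 21 macrophage markers 5 rose, 9 adjusted over the list alone, with a median of 1.23 and MRC1 (CD206) up 5.66-fold (SE 0.60 on the log2 scale). The macrophage score of 1 PV library lay far above the others, and without it the median was 0.47 and 0 were called in edgeR. Of 22 platelet markers 12 rose, 16 adjusted over the list alone, with a median of 2.55, but without the PV library of highest platelet score the median was 0.75 and 0 were called in edgeR. Mitochondrially encoded genes had a median of 0.86, with 1 of 13 called (MT-ATP8, 1.33 ± 0.36) and 13 adjusted over the list alone. The macrophage, platelet and mitochondrial lists also had adjusted p = 0.271 with an estimated correlation.

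ERK-induced genes rose in 4 of 20 cases in PV, 6 adjusted over the list alone, with EGR3 up by 3.19 ± 0.72 and the ERK phosphatase gene DUSP5 by 2.68 ± 0.62 (adjusted p = 0.317 with an estimated correlation). TNF and NF-kB targets rose in 4 of 33 cases, among them ICAM1 (2.16 ± 0.49) and IL6 (3.38 ± 0.83), with adjusted p = 0.475 with an estimated correlation. JAK-STAT targets rose in 2 of 24 cases, 6 adjusted over the list alone, and fibrosis-linked genes in 2 of 28, 4 adjusted over the list alone. These had adjusted p = 0.36 and adjusted p = 0.326 with an estimated correlation. Of 21 classical monocyte genes none passed singly in edgeR, 3 were lower when adjusted over the list alone, and the list median was -0.37 (adjusted p = 0.271 with an estimated correlation). Genes called lower included JUN (-2.05 ± 0.56), FOS (-1.17 ± 0.33), HAL (-1.17 ± 0.32), the iron and manganese transporter gene SLC11A1 (-0.85 ± 0.21), NUAK2 (-1.50 ± 0.43), ARHGEF40 (-0.89 ± 0.24), CD300LB (-0.88 ± 0.25), ABTB1 (-0.88 ± 0.22), ABHD5 (-0.79 ± 0.18) and UBXN2B (-0.78 ± 0.20). Cell-cycle genes had a median of 0.32 and none passed in edgeR, and the list was not called in camera.

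The edgeR test called 445 genes in PV against NBM, 391 higher and 54 lower, 374 of them by at least 1 on the log2 scale. Without the library of lowest depth, a PV library left out after seeing the data, 320 genes passed. Then ABHD5 alone of the 10 lower genes just named passed, the other 9 having adjusted p from 0.0577 (ABTB1, -0.80 ± 0.23) to 0.126 (CD300LB, -0.79 ± 0.26), and IFIH1, HLA-DPA1 and MT-ATP8 lost their calls at 1.002 ± 0.296, 1.28 ± 0.37 and 1.27 ± 0.38. When the PV library of highest platelet score was left out 285 passed, 254 higher and 31 lower. The calls then lost include JUN (-1.99 ± 0.60), FOS (-1.24 ± 0.35), HAL (-1.19 ± 0.34), ARHGEF40 (-0.84 ± 0.25), CD300LB (-0.88 ± 0.27), UBXN2B (-0.77 ± 0.22) and MT-ATP8 (1.31 ± 0.38), with adjusted p from 0.0569 to 0.0812, and the fibrosis-linked list (adjusted p = 0.0926). With that of highest macrophage score left out 118 passed, 111 higher and 7 lower. Each of the 10 lower genes but ABHD5 then lost its call, and so did EGR3 (2.54 ± 0.72), DUSP5 (1.92 ± 0.61), ICAM1 (1.64 ± 0.49), IL6 (2.53 ± 0.82), SOCS1 (3.66 ± 1.18), IDO1 (3.72 ± 1.21), IFIT5 (1.06 ± 0.38), IFI27 (2.83 ± 1.22), IFIH1 (0.77 ± 0.29), HLA-DOA (1.75 ± 0.46), HLA-DPA1 (1.04 ± 0.37), MRC1 (1.96 ± 0.60), MT-ATP8 (1.08 ± 0.38) and the fibrosis-linked list (adjusted p = 0.131). With that of lowest glycolysis score left out 512 passed, and JUN, NUAK2, HAL, FOS, CD300LB and UBXN2B lost their calls, with adjusted p from 0.0543 to 0.0856, as did the fibrosis-linked list (adjusted p = 0.0641). With 6 other-cell scores as covariates 13 passed, limma voom called 48, and the mitochondrial share as a covariate, chosen after seeing the data, left 283. Within the 58 libraries outside the technical set 374 passed, 315 of them among the 445, and 548 passed with the set as a term, while disease and tissue cannot be separated.

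ET against NBM asked the same for essential thrombocythemia. Some platelet genes and mitochondrially encoded genes were higher in ET (n = 15) than in NBM (n = 14). No list was called with an estimated correlation. PPBP rose by 4.50 ± 0.66 (22.6-fold, adjusted p = 0.00011) and lay above the NBM median in 93.3% of ET libraries. CLU rose by 3.02 ± 0.49, PF4 by 3.01 ± 0.60, MPIG6B by 2.73 ± 0.52 and ITGA2B by 2.13 ± 0.54. EGR2 rose by 2.44 ± 0.60, DUSP2, a MAP kinase phosphatase, by 1.97 ± 0.46, NR4A1 by 1.49 ± 0.39 and RRAS by 1.27 ± 0.31.

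Of 22 platelet and megakaryocyte markers 13 rose in ET, 17 adjusted over the list alone, with a median of 2.57. Of 13 mitochondrially encoded genes 7 rose, 13 adjusted over the list alone, with MT-ATP8 up by 1.45 ± 0.32 and MT-CO2 by 1.26 ± 0.29. Each of these lists just missed with an estimated correlation (adjusted p = 0.0507). TNF and NF-kB targets rose in 3 of 33 cases, CXCL3 by 2.80 ± 0.58, CXCL2 by 2.44 ± 0.59 and NFKB2 by 1.06 ± 0.27, and 11 passed when adjusted over the list alone (adjusted p = 0.553 with an estimated correlation). ERK-induced genes had a median of 0.75, with 1 of 20 called and 4 adjusted over the list alone (adjusted p = 0.374 with an estimated correlation). Of the 20 RSK and ERK kinases 1 rose, MAP2K2 by 0.78 ± 0.20 (adjusted p = 0.042), which stood at 0.24 ± 0.21 and was not called within the 58 libraries outside the technical set. Adjusted over the list alone PDPK1, RPS6KA4 and HRAS rose as well, and that list was not called. Macrophage markers rose in 3 of 21 cases, with APOE up by 2.42 ± 0.63, and 13 passed when adjusted over the list alone (adjusted p = 0.393 with an estimated correlation). JAK-STAT targets, fibrosis-linked genes and non-classical monocyte genes were called higher, with medians of 0.22, 0.42 and 0.47 and 0, 1 and 1 genes past edgeR, and classical monocyte genes lower, with a median of -0.16 and none past edgeR. These 4 lists had adjusted p = 0.585, 0.374, 0.553 and 0.585 with an estimated correlation. Type I and gamma interferon lists had medians of -0.31 and 0.05 and were not called. Cell-cycle genes had a median of -0.01, with none past the edgeR test. Of 22 erythroid markers 1 fell, and 1 rose and 1 fell when adjusted over the list alone (adjusted p = 0.585 with an estimated correlation). The lower genes named here changed little, although 19 of the 33 genes called lower changed by at least 1 on the log2 scale. ANXA6 stood at -0.72 ± 0.19, UBXN2B at -0.68 ± 0.17, INTS6 at -0.65 ± 0.16, USF3 at -0.54 ± 0.14, CCNC (cyclin C) at -0.51 ± 0.12, TIA1 at -0.49 ± 0.13, CPSF7 at -0.48 ± 0.10, EPS15 at -0.48 ± 0.12, and GATAD2B at -0.45 ± 0.10.

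The edgeR test called 199 genes in ET against NBM, 166 higher and 33 lower, 139 of them by at least 1 on the log2 scale. The technical set holds 7 of the 15 ET libraries, and within the 58 libraries outside it 13 genes passed, 12 of them among the 199, with 6 platelet markers called (1219 genes at an unadjusted p under 0.05). With the set as a term 30 passed, with log2 library size as a covariate 52, with the mitochondrial share 15 and with 6 other-cell scores 1, and disease and tissue cannot be separated.

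Across the 3 diseases, 51 genes were higher and 2 lower in every comparison with NBM. PPBP, PF4, CLU, MPIG6B, EGR2, DUSP2 and PDGFA were among those higher, and UBXN2B among those lower. Of these, PPBP, PF4 and MPIG6B are platelet genes, and platelets also carry CLU and PDGFA. Each comparison also set cells stated as blood against cells from marrow. Platelet carry-over, tissue and a change common to the diseases can therefore not be told apart in this overlap. Independent lists of the same sizes would share 0.136 and 0.00253 genes, which ignores that the 3 comparisons have their NBM libraries in common. In 10 simulations with no effect, with simulated NBM libraries common to the 3 comparisons, 0 genes were shared. Few genes are called in such data, so this 0 cannot show what the common libraries add. With the NBM libraries split into 3 parts, 1 for each disease, 0 genes were shared in 5 random divisions, a setting with few NBM libraries per comparison. With 6 other-cell scores as covariates 0 genes were shared, and 7 were shared within the 58 libraries outside the technical set, chosen after seeing the data. With the PV library of highest platelet score left out 18 were shared, 17 higher and 1 lower, and PPBP, PF4, MPIG6B, PDGFA and UBXN2B were not among them. With that of highest macrophage score left out 30 were shared, 29 higher and 1 lower, without DUSP2 and UBXN2B.

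**Figure D3:**
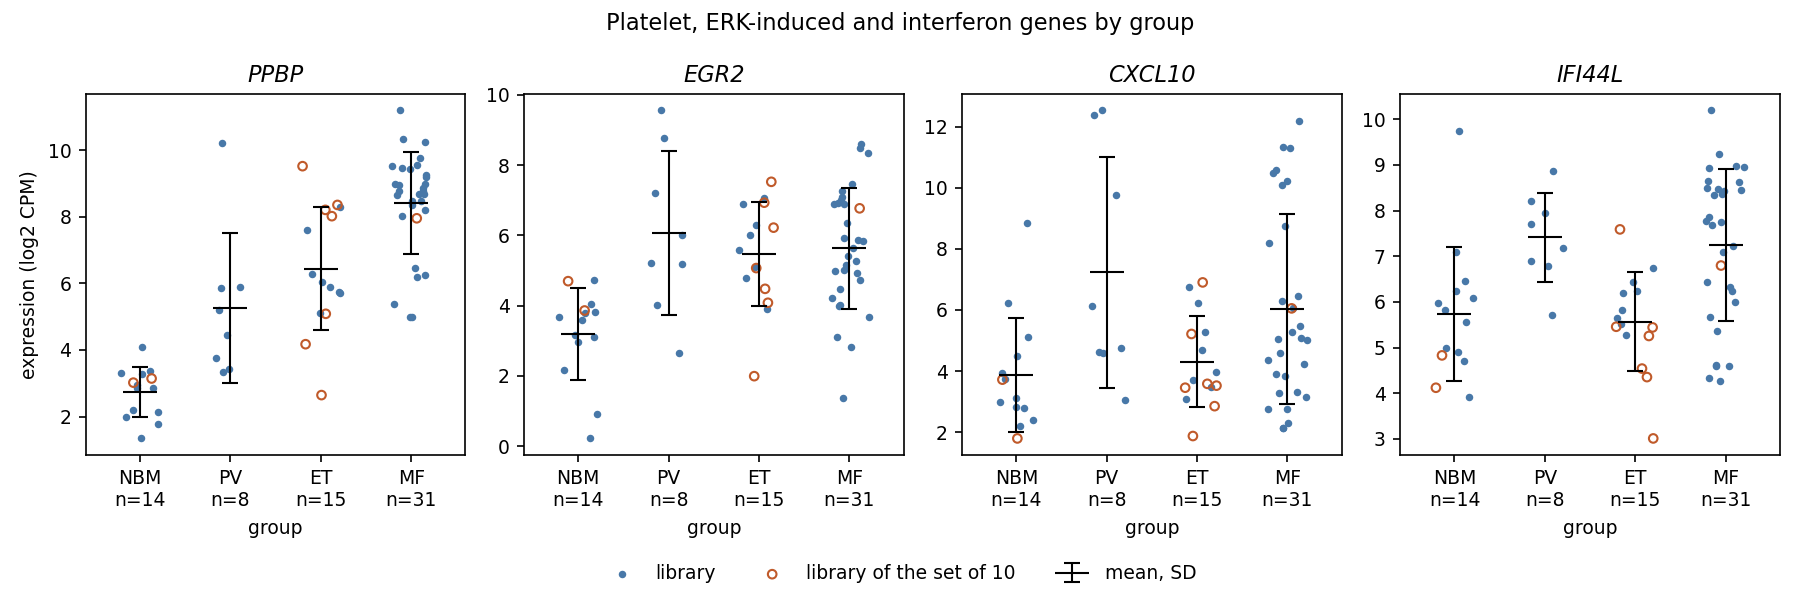
Expression in log2 CPM (vertical axis) of PPBP, EGR2, CXCL10 and IFI44L by group, with 1 point per library, open circles for the 10 libraries of the technical set, and the mean with its SD. PPBP is above the NBM median in 100% of MF and PV libraries and in 93.3% of ET libraries.

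MF against ET compared 2 patient groups whose cells were both stated to come from blood. Some interferon and platelet genes were higher in MF (n = 31) than in ET (n = 15), and some cell-cycle, B cell, plasma cell and neutrophil precursor genes were lower. No list was called with an estimated correlation. RSAD2 (viperin), an antiviral interferon-induced gene, rose by 3.81 ± 0.83 (14-fold, adjusted p = 0.0016) and lay above the ET median in 80.6% of MF libraries. Mean log2 CPM lay closer together than the fitted folds, at 5.37 in MF and 3.32 in ET for RSAD2, and 7.83 and 6.11 for IFIT3. IFIT3 rose by 2.93 ± 0.68, IFI44L by 2.08 ± 0.49, GBP4 by 2.05 ± 0.46 and PF4 by 2.34 ± 0.52. Lower genes were MPO (-1.87 ± 0.34), the lipolysis inhibitor gene G0S2 (-1.75 ± 0.53), HP (-1.67 ± 0.46), NR4A2 (-1.57 ± 0.23) and H4C3 (-1.49 ± 0.21).

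Of 34 type I interferon genes 25 rose in MF over ET, 31 adjusted over the list alone, with a median of 1.32 and OAS2 up by 1.28 ± 0.26. Of 22 interferon gamma genes 13 rose, 18 adjusted over the list alone, with a median of 1.37 and CXCL11 up by 3.78 ± 0.82. MHC class II genes rose in 7 of 15 cases and 1 fell, with HLA-DRA up by 0.83 ± 0.23. These 3 lists had adjusted p = 0.214, adjusted p = 0.39 and adjusted p = 0.548 with an estimated correlation. Platelet markers rose in 9 of 22 cases, 16 adjusted over the list alone, with GP1BA up by 1.92 ± 0.32 (adjusted p = 0.214 with an estimated correlation). Non-classical monocyte genes rose in 7 of 21 cases and 1 fell, with SIGLEC10 up by 0.75 ± 0.18 (adjusted p = 0.299 with an estimated correlation). Classical monocyte genes fell in 5 of 21 cases and rose in 2, with a median of -0.11 (adjusted p = 0.559 with an estimated correlation). Mitochondrially encoded genes fell in 7 of 13 cases, 12 adjusted over the list alone, with a median of -0.60 (adjusted p = 0.214 with an estimated correlation). RPS6KA2 fell by 0.65 ± 0.20 on the log2 scale in MF against ET (adjusted p = 0.025), from 1.83 ± 0.60 log2 CPM in ET to 1.12 ± 0.74 in MF. Of the kinase list 2 genes rose, among them NRAS by 0.65 ± 0.15, and the other gene that fell was MAP2K2 (-0.59 ± 0.17), which stood at 0.01 ± 0.19 within the 58 libraries outside the technical set. The list itself was not called. DUSP6 stood at 0.80 ± 0.28 (adjusted p = 0.051).

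Cell-cycle genes fell in 21 of 32 cases in MF against ET, 25 adjusted over the list alone, with a median of -1.17 and TOP2A at -2.15 ± 0.37. Of 19 B cell markers 6 fell, 11 adjusted over the list alone, with DNTT at -6.87 ± 0.66 and VPREB1, part of the pre-B cell receptor, at -5.64 ± 0.59. Of 14 plasma cell markers 6 fell, with IGKC at -3.43 ± 0.71. These 3 lists each had adjusted p = 0.214 with an estimated correlation. Of 22 erythroid markers 8 fell and 1 rose (adjusted p = 0.264 with an estimated correlation). Of 25 neutrophil precursor markers 7 fell, with PRTN3 (proteinase 3) at -3.82 ± 0.66 (adjusted p = 0.373 with an estimated correlation). Stromal and endothelial markers fell in 6 of 18 cases and rose in 2, with CXCL12, a chemokine of marrow stroma, at -4.27 ± 0.58 and COL1A1 at -3.25 ± 0.48 (adjusted p = 0.39 with an estimated correlation). Macrophage markers fell in 6 of 21 cases, with VCAM1 at -4.48 ± 0.78 and SELENOP at -2.61 ± 0.45 (adjusted p = 0.468 with an estimated correlation).

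The edgeR test called 2384 genes in MF against ET, 1227 higher and 1157 lower, 889 of them by at least 1 on the log2 scale. Within the 58 libraries outside the technical set 548 passed, 432 of them among the 2384, the type I interferon list had a median of 1.54 with 3 members called and the cell-cycle list -0.997 with 7. With the set as a term 972 genes passed, with log2 library size as a covariate 513, and with 6 other-cell scores 105, and with the mitochondrial share 1012.

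**Figure D4:**
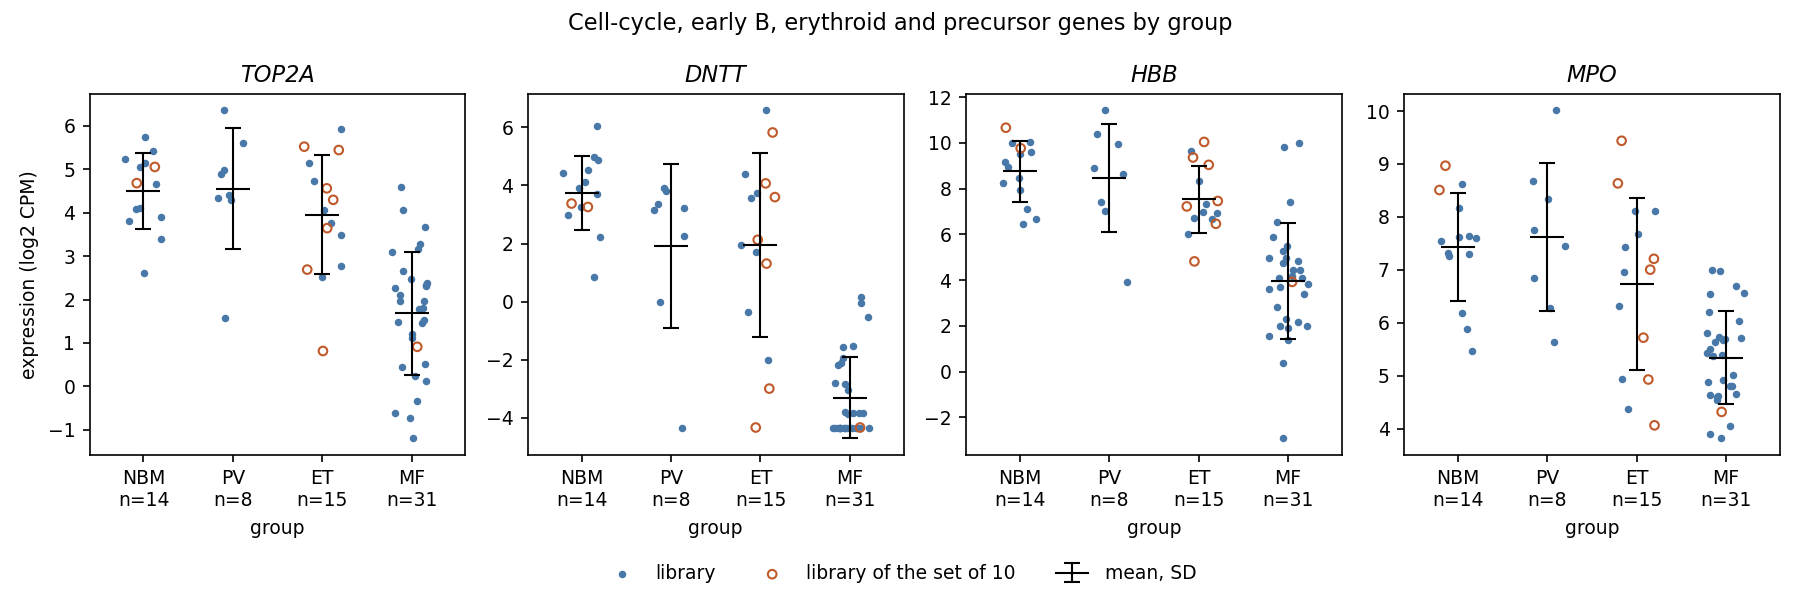
Expression in log2 CPM (vertical axis) of TOP2A, DNTT, HBB and MPO by group, with 1 point per library, open circles for the 10 libraries of the technical set, and the mean with its SD. MPO is below the NBM, ET and PV medians in 100% of MF libraries, and the lowest points of DNTT are libraries without counts.

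MF against PV compared myelofibrosis with the smaller group of polycythemia vera, both stated as blood. Many erythroid, plasma cell and cell-cycle genes were lower in MF (n = 31) than in PV (n = 8), and some non-classical monocyte and platelet genes were higher. HBB fell by 3.20 ± 0.73 on the log2 scale (9.18-fold lower, adjusted p = 0.0035) and lay below the PV median in 93.5% of MF libraries. MPO stood at -2.63 ± 0.39, NR4A2 at -1.51 ± 0.28, PRDX2, a peroxidase abundant in red cells, at -1.51 ± 0.30, and STMN1, a tubulin regulator of dividing cells, at -1.44 ± 0.43. Higher genes were PTGIR, the prostacyclin receptor (1.36 ± 0.35), GPR35 (1.36 ± 0.39), ECE1 (1.23 ± 0.27), ADGRE1 (1.19 ± 0.22) and MTSS1 (1.18 ± 0.28).

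In MF against PV 5 lists kept their calls with an estimated correlation, each with adjusted p = 0.0475. These were cell cycle (23 of 32 fell, median -1.49), erythroid markers (12 of 22 fell, median -2.66), plasma cell markers (9 of 14 fell, median -3.04), platelet markers (3 of 22 rose, median 1.53) and non-classical monocyte genes (6 of 21 rose, median 0.75). Adjusted over the list alone the counts were 29, 15 and 12 lower and 12 and 11 higher. AURKB stood at -1.97 ± 0.28, SDC1 (CD138 of plasma cells) at -5.90 ± 0.75, GP1BA at 2.07 ± 0.42 and CDKN1C at 2.07 ± 0.49. B cell markers fell in 7 of 19 cases, 13 adjusted over the list alone, with DNTT at -5.83 ± 0.69 (adjusted p = 0.206 with an estimated correlation). Neutrophil precursor markers fell in 3 of 25 cases and macrophage markers in 5 of 21, with SELENOP at -2.53 ± 0.53 (adjusted p = 0.121 and adjusted p = 0.174 with an estimated correlation). Of the 20 RSK and ERK kinases none passed singly in edgeR, 6 were higher when adjusted over the list alone, and the median was 0.20 (adjusted p = 0.0582 with an estimated correlation). Homing and adhesion genes rose in 1 of 27 cases, ITGAX (CD11c) by 0.53 ± 0.16, with 3 adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). The homing score of 1 PV library lay far below the others, and without it, which also had the lowest glycolysis score, the list lost its call (adjusted p = 0.16). Both interferon lists were not called, with medians of 0.25 and -0.30. DUSP6 stood at 0.43 ± 0.35 and RPS6KA3 at 0.10 ± 0.13.

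The edgeR test called 825 genes in MF against PV, 209 higher and 616 lower, 552 of them by at least 1 on the log2 scale. Within the 58 libraries outside the technical set 872 passed, 758 of them among the 825, and 973 passed with the set as a term. With 6 other-cell scores as covariates 15 passed, without the other-cell genes 515 did, and a fit of these groups alone gave 452. Without the library of lowest depth, a PV library, 584 passed, with STMN1 at -1.36 ± 0.45 and ITGAX at 0.46 ± 0.17 no longer called. Without the PV library of highest platelet score 622 passed, and HBB (-2.56 ± 0.76, adjusted p = 0.0535), GPR35 (1.29 ± 0.42), STMN1 (-1.04 ± 0.45) and ITGAX (0.44 ± 0.17) lost their calls. The platelet list then had a median of 2.71 with 18 of 22 called. With that of highest macrophage score left out 572 passed, without GPR35 (1.31 ± 0.42) and STMN1 (-1.36 ± 0.45), and 1 macrophage marker was called (median -0.02). With that of lowest glycolysis score left out 850 passed, without GPR35 (1.24 ± 0.41) and ITGAX (0.50 ± 0.17).

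PV against ET compared the remaining pair of patient groups. Few genes differed between PV (n = 8) and ET (n = 15), and chance was not excluded, since 2 of 30 splits of these libraries, the real one included, called at least as many. The genes named here were called in the fit of all 68 libraries. CXCL10 rose by 5.53 ± 1.22 (46.3-fold, adjusted p = 0.028) and lay above the ET median in 87.5% of PV libraries. In 3 of 8 PV libraries it lay above every ET library and in the other 5 within the ET range, and mean log2 CPM differed by 2.92. RSAD2 rose by 4.51 ± 0.95 and lay above the ET median in 100% of PV libraries, with mean log2 CPM of 5.77 in PV and 3.32 in ET. NCOA7 rose by 2.31 ± 0.47 and NASP, a histone chaperone gene, by 0.59 ± 0.12, and FOXK2, a forkhead repressor gene, fell by 0.67 ± 0.14 on the log2 scale. CXCL11 rose by 4.89 ± 0.95. Of 22 interferon gamma genes 2 rose and of 34 type I genes 1 did, against 19 and 11 adjusted over the list alone, with medians of 1.40 and 0.92 (adjusted p = 0.766 with an estimated correlation for each). MHC class II genes had a median of 0.68, with none past edgeR and 9 adjusted over the list alone (adjusted p = 0.766 with an estimated correlation). Non-classical and classical monocyte lists were called lower in PV, with medians of -0.38 and -0.27 and no gene past edgeR, and the cell-cycle list higher with a median of 0.38 (adjusted p = 0.91 with an estimated correlation for each). Erythroid markers were called higher (median 1.32) and platelet markers lower (median -0.04), with no gene past edgeR, and T cell markers were called lower by camera although their median was 0.76 and their mean 0.79 (adjusted p = 0.91 with an estimated correlation for each). RPS6KA2 and RPS6KA3 stood at -0.45 ± 0.29 and -0.02 ± 0.14, and DUSP6 at 0.37 ± 0.37.

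The edgeR test called 40 genes in PV against ET, 35 higher and 5 lower, 37 of them by at least 1 on the log2 scale. There were 3308 at an unadjusted p under 0.05. DESeq2 called 270, 133 higher and 137 lower, and 23 of the 40 were among them. Without the PV library of highest platelet score 35 passed, NASP lost its call (0.53 ± 0.13, adjusted p = 0.0572), and so did the erythroid, cell-cycle and classical monocyte lists (adjusted p = 0.0905, 0.163 and 0.066). With that of highest macrophage score left out 2 passed, and CXCL10 (4.74 ± 1.20), RSAD2 (2.93 ± 0.90), NCOA7 (1.59 ± 0.46), NASP (0.46 ± 0.12), FOXK2 (-0.67 ± 0.15) and CXCL11 (4.17 ± 0.95) lost their calls, with adjusted p from 0.0511 to 0.17. With that of lowest glycolysis score left out 99 passed, and the classical monocyte list lost its call (adjusted p = 0.292). Within the 58 libraries outside the technical set, which hold every PV and 8 ET libraries, 0 genes passed in edgeR (1559 at an unadjusted p under 0.05). With the set as a term 0 passed as well, with 1713 at that p.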

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

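The comparison of groups with the tissue as stated, the search for marrow transcripts in PV and ET, the tests of the technical set and of GC content for ET against NBM, and the splits for MF against NBM were chosen only after the result was seen. The other tests here were fixed before their result was seen. After a median over genes, ± gives the median SE of the single genes, not an error of the median.

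Many cell-cycle genes were lower in MF than in NBM, and also than in ET and PV. Between the diseases the cell-cycle list passed a test of the difference (median -1.17 in MF against ET and -1.49 in MF against PV). With an estimated correlation the camera adjusted p was 0.214 and 0.0475. The call was thus lost in MF against ET, as it also was in MF against NBM. The stated sources, marrow for NBM and blood for every patient, are argued against as the whole cause, since between groups both stated as blood 21 of 32 cell-cycle genes were called lower in MF against ET and 23 in MF against PV (7 and 21 within the 58 libraries outside the technical set). A score of 5 lists was the mean centred log2 CPM of their members, with each list weighted equally. The lists were cell cycle, erythroid, B cell, plasma cell, and stromal and endothelial markers. They were chosen because they were lower in MF than in ET and PV. The score stood at -1.38 ± 0.30 (SE) in MF against ET and -1.67 ± 0.55 in MF against PV, which is no test. It stays open whether PV and ET samples may include marrow, or whether these diseases release precursors into blood: 13 of 23 PV and ET libraries lay above every MF library in 4 early B cell genes, and 9 of 23 in 7 stromal genes, against 12 and 2 of 14 NBM libraries, so the stromal count is a poor mark of marrow. A smaller share of other cells in MF cannot be told apart from fewer dividing monocytes, since with 6 other-cell scores the cell-cycle median in MF against ET went from -1.17 ± 0.35 to -0.38 ± 0.34 and its calls from 21 to 0, while those scores themselves differ between the groups.

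Interferon genes were higher in MF than in ET, with medians of 1.32 (type I) and 1.37 (gamma), both past a test of the difference, although both lost their call with an estimated correlation (adjusted p = 0.214 and 0.39). The technical set, which holds 7 ET libraries, is argued against as the whole cause of the type I change. Within the 58 libraries outside it the median of the fitted folds was 1.54 ± 0.48 against 1.32 ± 0.36 before. Calls nevertheless went from 25 to 3 (gamma list, 13 to 0) as the SE widened and ET shrank to 8 libraries. A part of the set in the change of single genes is not excluded. Other cells in the fraction stay open, since with 6 other-cell scores the type I median was 0.83 ± 0.50 and calls went from 25 to 0. A stronger interferon response of MF monocytes remains an untested biological explanation, and 83.9% of MF libraries had a type I score above the ET median. In PV that share was 100%.

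The calls in ET against NBM went with GC content, with a Spearman rho of 0.546 between log2 fold change and GC across genes and a median GC of 53.3% in called genes against 47.3% in tested ones. The technical set and GC content stay open as the cause of many of these calls: with the set as a term the median change in the called direction was 1.28 ± 0.36 against 1.44 ± 0.35 (rho 0.104), and 1.21 ± 0.35 with each library's GC slope as a covariate, but these genes had been chosen in the same libraries. Calls went from 199 to 30 and 29 under these terms, and within the 58 libraries outside the set to 13. There 1219 genes had an unadjusted edgeR p under 0.05, about what chance gives over the 24654 genes of the main fit. Genes were filtered anew in those libraries, so the number tested there may differ. Those 13 genes, 6 of them platelet markers, cannot come from the set. Platelet carry-over, a tissue difference or the disease may each account for the 13 platelet markers called (9 markers with either term), and the design cannot separate them.

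Other differences between diseases were smaller. RPS6KA2 stood at -0.65 in MF against ET. The non-classical monocyte list had medians of 0.40 in MF against ET and 0.75 in MF against PV. Medians of mitochondrially encoded genes were -0.60 and -0.52. In MF against PV the medians were 0.20 for the RSK and ERK kinases and 0.28 for the homing and adhesion genes. ITGAX was the only member of these last lists past edgeR there. These passed a test of the difference, edgeR for the gene and both camera and fry for the lists. With an estimated correlation the lists lost their calls, except the non-classical genes in MF against PV (adjusted p = 0.0475): non-classical genes in MF against ET (0.299), mitochondrially encoded genes (0.214 and 0.241), kinases (0.0582) and homing genes (0.284). The homing list also lost its call without the PV library of lowest glycolysis score (0.16).

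In the group of 8 PV libraries, 8 of 75 values tested had a single library far from the others, by the ratio of its gap to the range (Dixon's 95% limit for 8 values). Chance alone gives about 1 in 20 per test. Highest libraries stood apart in the scores of macrophage markers (0.689), NK cell markers (0.638), platelet and megakaryocyte markers (0.634) and T cell markers (0.553), and in PPBP (0.629) and PF4 (0.542). Lowest libraries stood apart in glycolysis (0.639) and in homing and adhesion (0.538). These came from 3 different libraries, 5 of them from 1, and no explanation was tested. Without the PV library of highest macrophage score the calls went from 445 to 118 in PV against NBM and from 40 to 2 in PV against ET. PPBP went from 4.56 ± 0.70 to 2.01 ± 0.58 and PF4 from 3.38 ± 0.66 to 1.12 ± 0.58 in PV against NBM without the PV library of highest platelet score, and neither was called.

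Splits of the libraries into groups of the same sizes were drawn 30 times per comparison, the real one included. In 5 comparisons 1 split, the real one, called as many genes: MF against NBM (2136, highest other 857), PV against NBM (445, 128), ET against NBM (199, 2), MF against ET (2384, 1976) and MF against PV (825, 126). With 30 splits, 1 in 30 is the smallest share that can be reached. This argues against chance in each of these comparisons without excluding it. The splits were drawn without regard to the technical set, so they cannot separate a difference between groups from one of the set. The set is uneven in ET against NBM (7 and 2 libraries) and in MF against ET (1 and 7). Without the PV library of highest macrophage score 118 genes passed in PV against NBM, and no splits were run without it. Whether the result of the splits there depends on that library is therefore open. For PV against ET the splits gave no argument against chance, since 2 of 30 called at least the real 40 genes. The highest other called 128. A split that calls several times the real count points to a structure of the samples, and this one put 4 technical-set libraries in the group of 8 and 3 in the group of 15, against 0 and 7 in the real one. The split of MF and ET that called 1976 genes put all 8 set libraries in the group of 31, which may follow the set in part, and within the 58 libraries outside it 548 genes passed in the real comparison.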

How the results depend on the processing

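The technical set as a term, the 58 libraries outside it, the GC slope, the mitochondrial share and the fits without the library of lowest depth or the PV libraries of highest platelet, highest macrophage or lowest glycolysis score were chosen only after the results were seen. The other alternatives were planned.

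RPS6KA1 passed in none of the 6 comparisons under any of 20 alternatives. Its log2 fold change ran from -0.07 to 0.03 in MF against NBM, -0.37 to -0.19 in PV against NBM, -0.24 to 0.09 in ET against NBM, -0.11 to 0.26 in MF against ET, 0.15 to 0.38 in MF against PV and -0.42 to 0.02 in PV against ET, with adjusted p from 0.304 to 1. Sign changes came in MF against NBM with limma voom (0.013), 6 other-cell covariates (0.0075), the set as a term (0.026) and the 58 libraries (0.034), in ET against NBM with 6 covariates (0.055) and the mitochondrial share (0.093), in MF against ET with 6 covariates (-0.047) and the mitochondrial share (-0.11), and in PV against ET with the set as a term (0.021, from -0.24 ± 0.18).

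DESeq2 size factors and upper-quartile factors left every count of genes within 1.5 times. No low-count filter gave 722 genes in PV against NBM, 382 in ET against NBM, 1468 in MF against PV and 211 in PV against ET, while the stricter filter, which tests fewer genes, gave 495 in MF against PV and 13 in PV against ET. The DESeq2 test called 678 in ET against NBM, 270 in PV against ET (23 of the 40 edgeR calls among them) and 101 in all 3 diseases. limma voom called 3738 in MF, 48 in PV and 544 in ET against NBM, 499 in MF against PV, 7 in all 3 diseases, and 0 in PV against ET (1975 at an unadjusted p under 0.05, against 40 calls in edgeR). Only the groups compared, a fit with fewer samples, gave 335 in ET against NBM, 452 in MF against PV and 0 in PV against ET (edgeR, 2578 at that p, against 270 in DESeq2 and 0 in voom with all groups).

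Against a fold of 1.5, a stricter question, glmTreat called 555, 112 and 33 genes in MF, PV and ET against NBM, 308 in MF against ET, 302 in MF against PV, 4 in PV against ET and 20 in all 3 diseases. With 6 other-cell covariates edgeR called 6, 13 and 1 against NBM, 105 in MF against ET, 15 in MF against PV, 0 in PV against ET (2925 at an unadjusted p under 0.05) and 0 in all 3 diseases. The groups explained 55.6% of the variance of the platelet score and 23.2% of the B cell score, so these covariates take out group differences too. For the 2136 genes of MF against NBM the median SE rose from 0.285 to 0.529. Leaving out other-cell genes gave 515 in MF against PV. Log2 library size as a covariate gave 52 in ET against NBM, 513 in MF against ET, 71 in PV against ET and 30 in all 3 diseases. Except where stated, the cause was not tested.

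Numbers of replicates do not pair the samples: 67 pairs of libraries with the same number had a median correlation of 0.005 (-0.34 to 0.37), and 4 of 52 libraries were closest to their own number. As a block, these numbers cost degrees of freedom and gave 844 genes in MF, 0 in PV (edgeR, 2782 at an unadjusted p under 0.05) and 78 in ET against NBM, 436 in MF against ET, 490 in MF against PV, 0 in PV against ET (3173) and 0 in all 3 diseases. Under the block RPS6KA1 stood at -0.021 in MF against ET, RPS6KA3 at 0.0041 and DUSP6 at -0.039 in PV against ET, and DUSP6 at -0.16 in PV against NBM.

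With the set as a term 30 genes passed in ET against NBM, 972 in MF against ET, 0 in PV against ET (edgeR, 1713 at an unadjusted p under 0.05) and 23 in all 3 diseases. Within the 58 libraries these were 13, 548, 0 (1559) and 7. The GC slope left 29 in ET against NBM and 22 in all 3 diseases. The mitochondrial share left 283 in PV and 15 in ET against NBM, 1012 in MF against ET, 136 in PV against ET and 6 in all 3 diseases. Without the PV library of highest platelet score 285 passed in PV against NBM and 18 in all 3 diseases, and 7 lists passed in PV against ET. Without that of highest macrophage score 118 passed in PV against NBM, 2 in PV against ET and 30 in all 3 diseases, and without that of lowest glycolysis score 99 in PV against ET. These left-out libraries stood far from the other PV libraries.

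Of the 18, 17 and 14 lists called in MF, PV and ET against NBM, and 17, 15 and 11 in MF against ET, MF against PV and PV against ET, camera with an estimated correlation called 1, 0, 0, 0, 5 and 0. That correlation also reflects differences between donors that members share, which may make the test strict. In fry 0 lists passed in PV against NBM, 2 in ET against NBM and 0 in PV against ET. With 6 covariates 6 program lists passed in MF against NBM, with the mitochondrial share 26 lists in ET against NBM, and with the GC slope 17 in PV against ET.

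Among genes not called, DUSP6 changed sign with 6 covariates in MF against NBM (-0.34), PV against NBM (-0.034) and MF against PV (-0.30), and in ET against NBM with library size (0.078) and the mitochondrial share (0.29). RPS6KA3 did so in MF against ET with library size (-0.032), the set as a term (-0.053), the 58 libraries (-0.054) and the mitochondrial share (-0.048), in MF against PV with library size (-0.022), and in PV against ET with 6 covariates (0.073) without the library of lowest depth (0.028) and without the PV library of highest macrophage score (0.022). RPS6KA2 did so in PV against NBM without that of lowest glycolysis score (-0.055). Among 166 called genes that the naming rule gave or the text names, counted once per comparison, MAP2K2 in MF against ET reversed, to 0.011 within the 58 libraries. All the others kept their direction in every alternative that tested them: calls held for 165 of 166 with DESeq2, 110 with voom, 5 with 6 covariates, 79 with the block, 125 with the set as a term, 105 in the 58 libraries, 151 without the library of lowest depth, and 151, 126 and 157 without the PV library of highest platelet, highest macrophage and lowest glycolysis score. PV, the smallest group, which holds the library of lowest depth (14842000 counts), is where the simulated recovery was lowest.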

Other observations

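The relation of RPS6KA1 with list scores within MF was searched for only after the comparisons had been seen, and its 2 further tests were set before their results were seen. Several lists not described above also changed. The cholesterol synthesis list was called higher in MF and ET against NBM, with medians of 0.25 and 0.17. Both calls were lost with an estimated correlation. Of 23 genes 5 rose in MF and 1 in ET, and 7 and 4 did when adjusted over the list alone. INSIG1, a sensor of cell sterol levels, rose by 1.22 ± 0.23 and 1.25 ± 0.25 (adjusted p = 0.392 and adjusted p = 0.553 for the list with an estimated correlation). Nuclear genes of oxidative phosphorylation were called higher in PV and ET against NBM and lower in MF against ET and PV, all with small medians (0.10, 0.09, -0.06 and -0.06), and with adjusted p = 0.637, 0.686, 0.699 and 0.872 with an estimated correlation. NDUFA3, a subunit of complex I, rose by 0.48 ± 0.12 in ET and stood at -0.44 ± 0.10 in MF against ET. Glycolysis genes had a median of -0.17 in PV against NBM and 0.15 in MF against PV, called in camera with no gene past edgeR (adjusted p = 0.633 and adjusted p = 0.62 with an estimated correlation). The glycolysis score of 1 PV library lay far below the others, and both calls were lost without it (adjusted p = 0.452 and adjusted p = 0.358).

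Lists without a camera call in any comparison still held single called genes. In the inflammasome and alarmin list 3 of 19 rose and 4 fell in MF against NBM (median 0.08), with S100A9 at -0.65 ± 0.15, and TXNIP, an inhibitor of thioredoxin, rose by 1.03 ± 0.17 in MF against ET. Of 27 immediate early and heat shock genes 3 rose and 5 fell in MF (median -0.08), with FOSB at -1.16 ± 0.21. Among 24 stress genes of unfolded proteins and amino acids HERPUD1 fell by 0.83 ± 0.12 on the log2 scale in MF (median 0.07). Among 23 iron and heme genes 2 rose and 3 fell in MF (median -0.04), with TFRC, the transferrin receptor, at -1.09 ± 0.23, and HMOX1, heme oxygenase, was higher by 0.81 ± 0.18 in MF than in PV. The hypoxia response had 1 gene higher and 1 lower of 21 in MF (median 0.03), with EGLN3 at 2.97 ± 0.53. Of 78 cytosolic ribosomal proteins 1 fell, RPLP1 at -0.30 ± 0.08, and the median was -0.02. Homing and adhesion genes, called in MF against PV alone, had 4 higher and 2 lower of 27 in MF against NBM (median 0.15), with the integrin gene ITGA4 at 0.70 ± 0.12.

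Markers of other cells changed as follows. Neutrophil precursor markers were called higher in PV and ET against NBM, with medians of 0.88 and 0.44, 2 and 0 of 25 past edgeR, and CEACAM1 at 1.91 ± 0.54 in PV, a call lost at 1.82 ± 0.56 without the PV library of lowest depth, at 1.90 ± 0.56 without that of highest platelet score and at 1.64 ± 0.56 without that of highest macrophage score (adjusted p = 0.36 and adjusted p = 0.746 with an estimated correlation). Dendritic cell markers were called higher in PV and ET (medians 0.40 and 0.33) and lower in MF against ET and PV (-0.43 and -0.34), with CLEC4C, of plasmacytoid dendritic cells, at -2.66 ± 0.49 in MF against ET (adjusted p = 0.271, 0.374, 0.214 and 0.174 with an estimated correlation). The dendritic list lost its calls in PV against NBM and MF against PV without the PV library of highest platelet score (adjusted p = 0.186 and adjusted p = 0.121), the stem and progenitor list in PV against ET (0.228) and the stromal list in MF against PV (0.185). These 4 calls were also lost without that of highest macrophage score (0.0666, 0.0548, 0.0964 and 0.0802), as was that of oxidative phosphorylation in MF against PV (0.262). Without that of lowest glycolysis score 3 of the 4, all but the dendritic one in MF against PV, were lost (0.0885, 0.0544 and 0.0714), and so was that of mature neutrophil markers in PV against ET (0.231). Mature neutrophil markers were called lower in MF and PV against NBM and in PV against ET, with medians of -0.26, -0.75 and -0.42, although FCGR3B was higher in MF by 1.54 ± 0.33 (adjusted p = 0.549, 0.271 and 0.91 with an estimated correlation). Stem and progenitor markers were called higher in PV against ET alone (median 0.40, adjusted p = 0.91 with an estimated correlation), and 4 of 21 rose in MF against NBM, with LAPTM4B at 1.93 ± 0.46. Stromal and endothelial markers, lower in MF against ET and also PV (median -0.68, adjusted p = 0.396 with an estimated correlation), had medians of -0.07, 0.54 and 0.50 in MF, PV and ET against NBM and no call. NK cell markers and basophil, eosinophil and mast cell markers were called in no comparison, with medians of -0.56 and 0.92 in MF, 0.75 and 0.35 in PV, and -0.14 and 0.34 in ET. T cell markers were called lower in MF against NBM and ET (medians -0.27 and -0.10, adjusted p = 0.759 and adjusted p = 0.699 with an estimated correlation).

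Median, mean and camera direction differed in sign for 44 of 210 combinations of list and comparison, 2 of them called. Both were T cell markers in PV, lower in camera against NBM and ET while their medians were 0.77 and 0.76. Camera works on log2 CPM, and the T cell score of 1 PV library lay far above the other 7, which raises fitted folds more than mean log values. High interferon scores were not confined to MF: 100% of PV, 83.9% of MF and 60% of ET libraries lay above the NBM median of the type I score, and 87.5%, 90.3% and 80% above that of the gamma score. For the ERK-induced score these were 62.5%, 80.6% and 80%.

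Although RPS6KA1 passed the test in no comparison of groups, its level varied among MF libraries with the ERK-induced score, which does not contain it. Across 31 MF libraries Pearson r was -0.755 (permutation p = 1e-05, the smallest they can give, adjusted p = 0.00023 over 23 relations tested) and Spearman rho -0.672 (p = 5e-05, adjusted p = 0.000575). The r was -0.653 without the 2 farthest libraries, -0.787 in the 30 libraries outside the technical set and -0.762 with the GC slope removed. In the 37 NBM, PV and ET libraries, as deviations from group means, r was -0.46 (p = 0.00412). By group it was -0.666 in ET (p = 0.00935, rho -0.629 with p = 0.0139, -0.564 without 2 libraries) and -0.229 in NBM (p = 0.424, rho -0.191), which misses the threshold, and -0.466 in the 8 PV libraries (rho -0.619). The technical set holds 7 ET, 2 NBM and no PV libraries. In ET, RPS6KA1 was mostly higher in the set (7.32 to 8.02 log2 CPM) than outside it (6.97 to 8.02). Values of r outside the set or with the GC slope removed are given for MF alone. A part of the set in the r of ET and of the 37 libraries is therefore not excluded.

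Among the other relations in MF, classical monocyte genes went up with RPS6KA1 (r 0.557, rho 0.738, adjusted p = 0.0136 and adjusted p = 0.00023). So did homing genes (0.522 and 0.584) and inflammasome genes (0.468 and 0.515), while fibrosis-linked genes (r -0.451) and JAK-STAT targets (r -0.435) passed by r alone, and so did hypoxia genes (r -0.468), whose r was 0.0416 without the 2 farthest libraries. A lower share of classical monocytes in some libraries might link the ERK-induced score with RPS6KA1. With the classical monocyte score removed from both, r in MF was -0.76 (permutation p = 1e-05). This argues against it only as far as that score follows their share. Scores of other cells were not among the relations tested. Counts per gene cannot show kinase activity, and the relation was found and tested in the same libraries.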
